A study of Caenorhabditis elegans with 2 samples.

How the data were processed

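ChIP-seq of GFP-tagged ELT-2 was done on whole L1 larvae in 2 biological replicates of 1 group, per the labels. The labels call the replicates biological, and no more is known of how the cultures were separated. Per the labels and the accompanying notes, each replicate's relaxed peak list derives from 1 alignment of that replicate and 1 control, the pooled list from both replicates, and the thresholded list from these 3 by the IDR procedure. All were supplied on the builds ce10 and ce11, which makes 8 peak lists. The aligner, peak caller, IDR threshold and their versions are not given in the sources used here, and neither the control reads nor the alignments were used here. In each deposited list the signal of a peak is the enrichment statistic the authors' peak caller gave, on a scale that differs between lists, and it is used only to rank, describe or divide peaks within a list. The −log10 q-value of each peak is likewise the authors' deposited value. It reaches a ceiling, shared by 3415 peaks of the pooled ce11 list, so it was not used for ranking. The files hold no read counts, so the depth per sample is unknown and no precision follows from it. Wilson intervals of shares cover counting error only.

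Coordinates are 1-based on ce11, the build of the reference used (WBcel235, Ensembl release 115 annotation with the RefSeq sequence). Lists on ce10 were counted, compared among themselves, set beside the length of X and compared with those on ce11 in peak width and signal values, with no coordinates converted. A summit is the peak position the authors recorded in each list. Transcript 5′ ends, exons and introns came from 19973 protein-coding genes on the 6 nuclear chromosomes. Where categories overlapped, a summit was assigned to promoter, then exon, then intron, then intergenic sequence. The gene symbols of the 16 lists were matched exactly to the annotation, where 424 matched and 2 did not. Another 97 symbols are shared by more than 1 protein-coding gene, and bound genes were counted by gene identifier.

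The main comparisons, their tests and most alternatives were fixed before the data were examined. Replicate agreement used the 5443 strongest peaks of each replicate, the number of thresholded peaks, and 1000 circular shifts of replicate 2 with a random offset per chromosome. Rank correlation used the strongest overlapping peak of each replicate at each thresholded peak and 10000 permutations. Promoter share and gene counts used a window of 1000 bp upstream to 200 bp downstream and 1000 circular shifts. The share on X was set against its share of nuclear length by an exact binomial test. The hexamer was sought within 50 bp of the summit, with flank windows centred 500 bp away, by an exact McNemar test. All hexamers were tested by Fisher exact tests against both flanks, with one-sided tails on a logarithmic scale for those too small to write. Gene lists were tested by Fisher exact tests. All tests are two-sided unless stated, adjusted p-values are by Benjamini-Hochberg within each family, and the threshold is 0.05.

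The rule for naming genes took every protein-coding gene whose promoter holds 1 of the 20 strongest promoter peaks, up to 4 bound members of each list with the strongest peak, up to 2 unbound members first in the alphabet, and always elt-2, elt-7, elt-4, end-1, end-3 and unc-119. The text names some of the genes this gives. Alternatives were other distances and promoter windows (500 and 100 bp, 3000 and 500 bp), summits given to the nearest 5′ end within 1000 bp, other motif windows (25 and 100 bp) and the degenerate motif WGATAR, the left flank, the ce10 lists, each replicate left out, and a stricter list of the 2721 strongest peaks. Leaving out a replicate means using the 5443 strongest peaks of the other. Restricting peaks to those with the hexamer, and the rank correlation over all overlapping relaxed peaks, were added after seeing the data.

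The programs were tested on simulated data before use. With summits planted in 60% of the members of 10 lists among 19973 genes, 100% of the planted lists and 0% of the others were called. Of 100 sets of 5000 random positions, 7% gave a promoter share with p under 0.05. Each planted hexamer was ranked first in 2000 windows, and none was called with nothing planted. The background positions were uniform, without the gathering at promoters or the base composition of real summits. These tests thus check the programs and do not bound false calls in the real data. The promoter check also used fewer shifts than the main test. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.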

Results

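The data map where the transcription factor ELT-2 sits on the genome of Caenorhabditis elegans at the start of larval life. ELT-2 is a zinc finger protein of the GATA family, named after the base sequence its members bind, and is the main regulator of gene expression in the worm intestine. The worms were hermaphrodites of strain OP56, which carries a transgene coding for ELT-2 with GFP and FLAG tags at its C-terminal end in an unc-119 mutant background. A working unc-119 gene normally serves as the visible marker of such transgenes. Hatchlings were synchronized by starvation after bleaching of the mothers and were collected as L1 larvae, the first larval stage, 6 h after synchronization. Tagged ELT-2 with its DNA was precipitated from whole worms by an antibody against GFP and the DNA was sequenced (ChIP-seq). There was 1 group with 2 biological replicates, so no conditions are compared. The questions are where peaks lay, how far the replicates shared them and which genes they accompanied. The files give peaks and not reads, so the sequencing depth of each replicate is unknown.

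The list that passed the irreproducible discovery rate procedure (IDR, which compares the ranks of peaks between replicates) held 5443 peaks on ce11, the genome build used throughout unless another is named. These are called ELT-2 peaks below. They covered 1961793 bp, or 1.96% of the nuclear genome, with a median width of 410 bp. The relaxed lists, which include background on purpose, held 17177 peaks for replicate 1, 18929 for replicate 2 and 16833 for both replicates pooled. Each peak's signal and q-value are the authors' own values and serve here to rank peaks within a list. The 5443 ELT-2 peaks were the 5443 strongest of the pooled list, with signals from 142 to 6412 and a median of 250.4. Of them, 5436 overlapped a peak of both replicates, 1 had no listed peak in replicate 1 and 6 had none in replicate 2. As the relaxed lists include background, overlap with any of their peaks is a lax criterion. By a stricter one, 84.9% of the ELT-2 peaks were among the 5443 strongest of both replicates. That share was 100% for the 1361 strongest ELT-2 peaks and 44.2% for the 1360 weakest.

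The first question was whether both replicates mark the same places. When each relaxed list was reduced to its 5443 strongest peaks, 81.2% of replicate 1 summits had a replicate 2 summit within 100 bp. Moving the replicate 2 summits along their chromosomes gave 1.12% on average and at most 1.69% in 1000 circular shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Signals of the replicate peaks at the same ELT-2 peak had a Spearman rho of 0.837 across 5436 peaks (two-sided permutation p = 0.0001, the smallest that 10000 permutations can give). These peaks were the strongest of the pooled list, to which both replicates contribute, and so were not chosen apart from the signals compared. Over all 12351 relaxed replicate 1 peaks that overlap a replicate 2 peak, rho was 0.761, a set added after seeing the data. Neighbouring peaks and genes are not independent replicates, so this and every later p describes the peaks of 1 experiment and not the spread between worms. The 3 strongest ELT-2 peaks ranked 1, 2 and 3 in each replicate too, led by a peak on chromosome II from 2378312 to 2379098.

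The 20 strongest promoter peaks stood beside genes of mixed kinds. The top peak lay 907 bp upstream of F16G10.6, with a signal of 6412, and the next lay 723 bp upstream of T24E12.13 on chromosome II, with a signal of 4173. Others among the 20 strongest promoter peaks lay 468 bp upstream of srz-62, of a family of predicted chemoreceptors, 658 bp upstream of fbxc-29, of an F-box family, and 262 bp upstream of clec-78, which codes for a C-type lectin. A peak on chromosome IV with a signal of 2427 was shared by cld-1 and dod-21, whose 5′ ends lay 292 and 175 bp away. The cathepsin B-like protease genes cpr-4 and cpr-3, both on chromosome V, had peaks 98 and 99 bp upstream with signals of 1692 and 1689. The glucosidase-related gene aagr-2 had one 327 bp upstream, and nhr-68, a nuclear receptor gene, had one 400 bp upstream with a signal of 1486, which lay nearer to H12C20.7, 50 bp away. A peak on chromosome V at 17659428 lay 43 bp upstream of fbxa-108 and 875 bp upstream of dgat-2, an acyltransferase gene of triglyceride synthesis. Of the 20 strongest peaks regardless of location, 10 lay outside promoters. Among these were the peak that ranked 4, on chromosome IV at 13919410 and 6381 bp from the nearest protein-coding 5′ end, and the peak that ranked 19, in an intron of pkg-2.

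ELT-2 peaks gathered at promoters and were rare in exons. A promoter was taken as 1000 bp upstream to 200 bp downstream of the 5′ end of any transcript of a protein-coding gene. Of the 5443 summits, 3076 lay there, which is 56.5% (95% Wilson interval 55.2 to 57.8) against 26.2% for circularly shifted summits, a 2.16-fold excess (two-sided permutation p = 0.001, the smallest 1000 shifts can give). Exons outside promoters held 255 summits, 4.68% against 21.6% for shifted summits, and introns held 820, 15.1% against 26.7%. The remaining 1292 summits, 23.7%, were intergenic, slightly below the shifted share of 25.5%. The permutation p-values were 0.001 for exons and introns and 0.013 for intergenic summits. The median distance from a summit to the nearest protein-coding 5′ end was 544 bp, and 70.7% of summits lay upstream of that end. With a window of 3000 bp upstream to 500 bp downstream the excess was 1.37-fold (79.0% against 57.7%). The intervals cover counting error only.

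**Figure D1:**
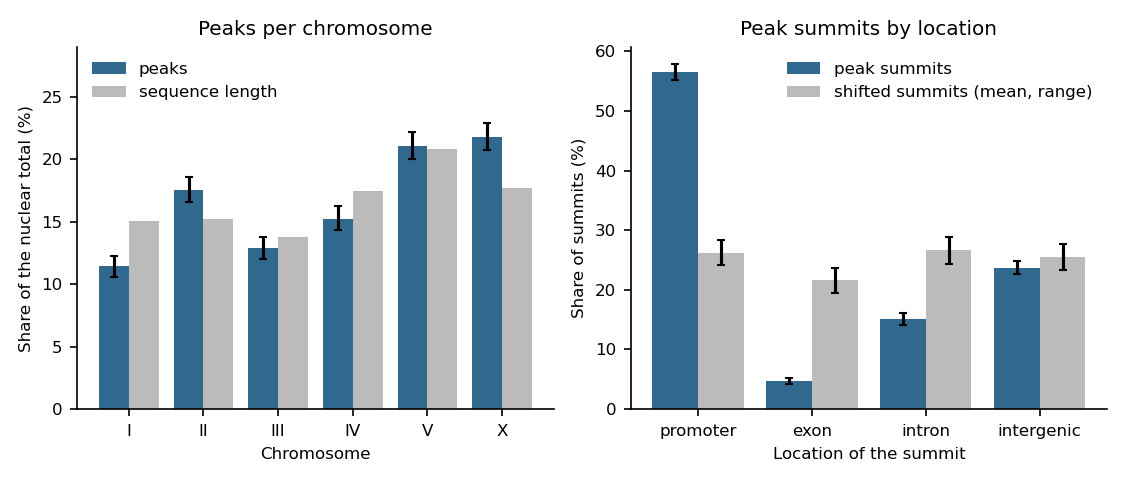
Left, share of the 5443 ELT-2 peaks on each chromosome in percent (blue, with 95% Wilson intervals) beside the share of nuclear sequence (grey). Right, share of summits by location in percent (blue, with 95% Wilson intervals) beside the mean and full range of 1000 circular shifts (grey). Chromosome X holds 21.8% of the peaks on 17.7% of the sequence, and promoters hold 56.5% of summits against 26.2% after shifting.

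Chromosome X carried more ELT-2 peaks than its length accounts for. It held 1188 peaks, 21.8% of all (95% Wilson interval 20.7 to 22.9) on 17.7% of the nuclear sequence (exact binomial test, two-sided, p = 5.7e-15). That is 67.05 peaks per Mb, the highest density, against 41.3 on chromosome I, the lowest, and 62.6 on chromosome II. Because X is poor in genes, the contrast per gene was wider, with 43.5 peaks per 100 protein-coding genes on X and 21.6 to 27.7 on the autosomes. Of the X peaks 45.7% lay in promoters and 29.9% in intergenic sequence, against 56.3% to 62.8% and 20.1% to 23.6% on the autosomes. This contrast was not tested, and X holds 14.7% of all promoter sequence, less than its share of length.

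The next question was whether ELT-2 peaks carry the sequence that GATA factors recognize. The hexamer TGATAA (TTATCA on the other strand), fixed before the data were examined, lay within 50 bp of the summit in 2451 of 5443 peaks, or 45.03% (95% Wilson interval 43.7 to 46.4). A window of the same width centred 500 bp to the right held it in 9.90%, a 4.55-fold difference (exact McNemar test, two-sided, log10 p = -366). The left flank held it in 10.4%. For the degenerate motif WGATAR the difference was 2.84-fold, with 57.7% against 20.3%. By location, TGATAA lay within 50 bp of 42.4% of promoter summits, the lowest share. It did so for 47.8% of exon, 51.1% of intron and 46.9% of intergenic summits, a contrast that was not tested. In a search of all 2080 hexamers, with both strands counted as one, the same TGATAA ranked first by p, at 45.03% of summits against 10.2% of flanks. CTTATC, which overlaps it by 5 bases and extends it by 1, came next with 32.02% against 3.98%. The base-10 logarithms of their one-sided Fisher exact p-values were -539 and -512. Around the 3473 copies of TGATAA at summits, the next base was G in 45.6% against 18.04% in the flanks and the preceding base was C in 37.5% against 21.5%. The search called 779 hexamers more frequent and 557 less frequent at summits (Fisher exact test, two-sided, Benjamini-Hochberg over 2080). Runs of A and T such as AAAATT were among the latter, with 24.0% against 43.8%.

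The hexamer became more frequent with peak signal. In 4 equal parts by signal, from strongest to weakest, it was at the summit in 53.4%, 48.6%, 41.0% and 37.1% of peaks, while the flank stayed between 9.40% and 10.4%. Across peaks the Spearman rho between signal and presence was 0.137 (two-sided permutation p = 0.0001, the smallest 10000 permutations can give). Strong peaks also held more copies, with a mean of 1.63 hexamers within 150 bp of the summit in the strongest part and 0.898 in the weakest. The 20 strongest peaks averaged 3.9 copies and 18 of them, 90%, held at least 2. Their right flank windows held the hexamer in 30% of cases, above the flank range of the 4 parts. The peaks at srz-62 and fbxc-29 held 7 copies each. Of the same 20 peaks 2 held no copy, the peak that ranked 12, on chromosome II from 5543413 to 5543919, and the peak that ranked 20, on chromosome II from 5844627 to 5845117. These lie over sls-2.2 and sls-2.1, genes of the spliced leader RNA SL2, and were singled out after their values were seen.

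**Figure D2:**
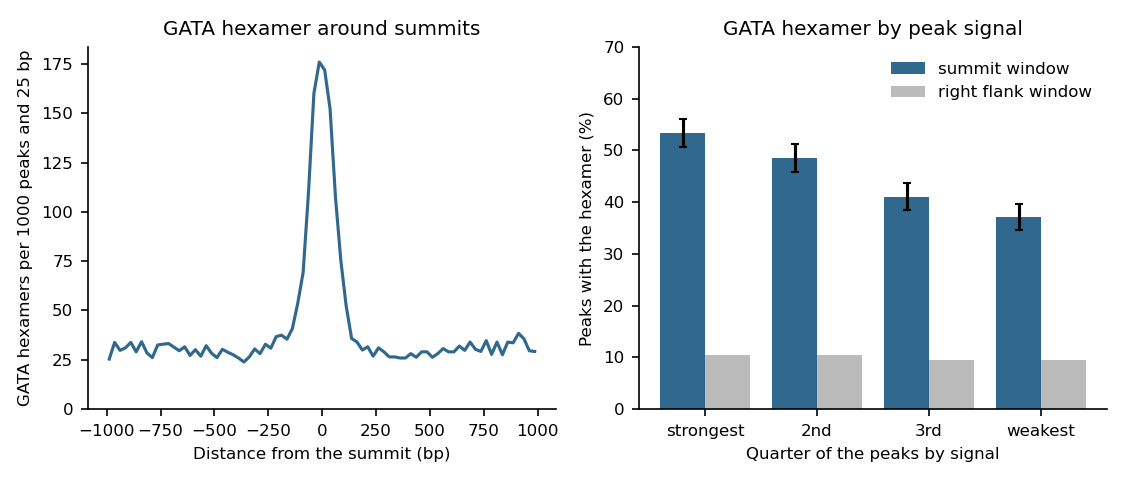
Left, number of GATA hexamers per 1000 ELT-2 peaks in bins of 25 bp, by distance from the summit in bp. Right, share of peaks with the hexamer within 50 bp of the summit in percent, in 4 equal parts by signal (blue, with 95% Wilson intervals), and in the right flank window (grey). The share falls from 53.4% in the strongest part to 37.1% in the weakest while the flank stays near 10%.

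ELT-2 peaks marked the promoters of genes that make the intestine absorb, digest and store. At least 1 summit lay in the promoter of 3401 of the 19973 protein-coding genes, 17.03%, and these are called bound. Shifted summits gave 1440 genes on average and at most 1581 (two-sided permutation p = 0.001, the smallest 1000 shifts can give). The 16 gene lists fixed before the data were examined were each tested against all other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the 16. Of these lists, 8 were bound more often than other genes and 2 less often.

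Structural and transport genes of the intestinal brush border, the absorptive surface of the gut, had the highest share. Of 21 genes 17 were bound, 81.0% against 16.96% of other genes (Fisher exact test, adjusted p = 1.2e-09). They included pept-1, the gut peptide transporter, with a peak 96 bp upstream (signal 835), the aquaporin gene aqp-1 (signal 753) and ifd-1, an intestinal intermediate filament gene (signal 668). The unbound members first in the alphabet were aqp-8 and erm-1. Of 29 digestive enzyme genes 20 were bound, 69.0% (Fisher exact test, adjusted p = 2.6e-09). Besides cpr-4 and cpr-3 these included the lysozyme gene lys-8, with a peak 173 bp upstream (signal 1337), and cpr-1 (signal 994), whereas the aspartyl protease genes asp-4 and asp-14 were unbound.

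Genes for metal, heme and xenobiotic handling were bound in 20 of 28 cases, 71.4%, and genes of lipid metabolism in 26 of 40, 65% (Fisher exact tests, adjusted p = 1.2e-09 and 1.5e-10). In the former, the heme transporter gene hrg-1 had a peak inside the gene, 116 bp upstream of an internal transcript start (signal 1087), and the metal transporter gene smf-3 one 76 bp upstream (signal 746), while cdr-1 and cdr-4 were unbound. In the latter, besides dgat-2, lbp-3, a fatty acid binding protein gene, had a peak 387 bp upstream (signal 1013) and the desaturase gene fat-4 one at an internal transcript start with a signal of 755. The lipase gene atgl-1 and the dehydrogenase gene acdh-2 were unbound. Of 25 immune effector genes 13 were bound, 52% (Fisher exact test, adjusted p = 0.00015). Among them were irg-4 (signal 939), a gene induced by infection, the saposin-like genes spp-8 and spp-5 (signals 821 and 782) and clec-67 (signal 735). Of 16 genes of gut granules, the lysosome-related organelles of intestinal cells, 8 were bound, 50% (Fisher exact test, adjusted p = 0.0049), with glo-4 (signal 310.1) and glo-3 (signal 293) first. The granule call did not hold with the 2721 strongest peaks (25%, Fisher exact test, adjusted p = 0.094).

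The genes listed beforehand as regulators of intestinal transcription were themselves bound in 13 of 20 cases, 65% (Fisher exact test, adjusted p = 6.2e-06). The 13 include elt-3 (signal 203) and daf-16 (signal 150.3). Whether each member acts mainly in the intestine was not checked. The strongest peaks lay at zip-10 (signal 790.4), nhr-8 (signal 771), a nuclear receptor gene of detoxification, nhr-80 (signal 587), one of fat metabolism whose peak lies nearer to the neighbour H10E21.1, and, at an internal transcript start, hlh-30 (signal 417), which controls lysosome and autophagy genes. Endodermal GATA factors as a group specify and maintain the gut lineage. Of the 7 genes listed as such, only elt-7 was bound, by a peak 1 bp from its 5′ end (signal 194, rank 3870 of 5443). The share of 14.3% was not separable from that of other genes (Fisher exact test, p and adjusted p = 1, 95% Wilson interval 2.57 to 51.3). It counts elt-2 and elt-4 as unbound, although the reason for their missing peaks is not known. For end-1 the only ELT-2 peak within 5000 bp of the gene lay 1856 bp downstream of its 5′ end, and for end-3 the nearest lay 2396 bp upstream. For med-1 the only one lay 4778 bp downstream (signal 199.7), and med-2 had none. For elt-2 itself and for elt-4, its neighbour on chromosome X, no list on ce11, relaxed ones included, held a peak within 5000 bp of the gene. At unc-119, on chromosome III, the pooled relaxed list held a single weak peak within 5000 bp (signal 60.02, rank 16227 of 16833) and the ELT-2 list none.

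**Figure D3:**
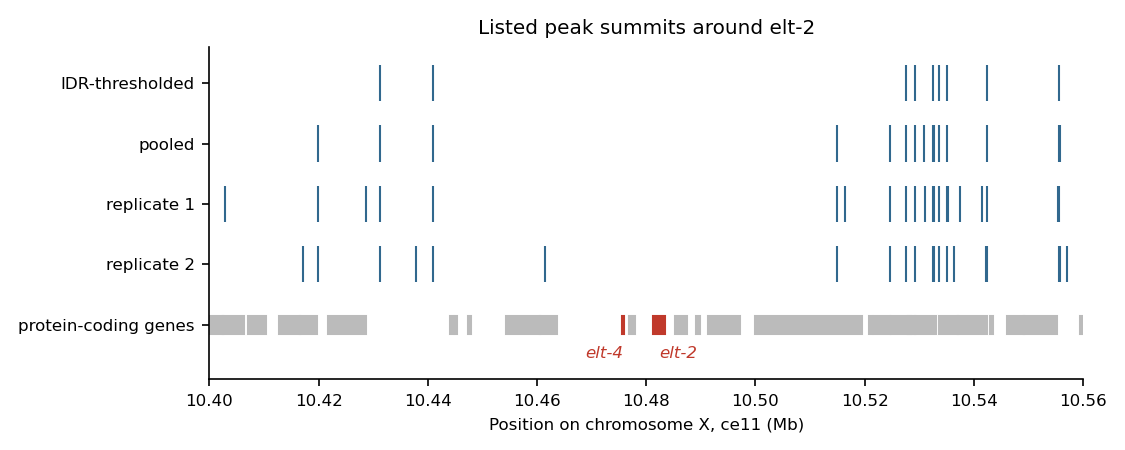
Summits of listed peaks on chromosome X around elt-2, by position in Mb on ce11. Each blue line is a summit, in the IDR-thresholded list, the pooled relaxed list and the relaxed lists of replicates 1 and 2, above protein-coding genes (grey, with elt-2 and elt-4 in red). No list has a summit between 10461441 and 10514914.

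None of the 6 vitellogenin genes, which code for yolk proteins made by the adult intestine, was bound (upper 95% Wilson limit 39.0%, Fisher exact test, adjusted p = 0.74). The nearest ELT-2 peak to vit-1 lay 2080 bp upstream (signal 1244, rank 52), in the promoter of the neighbouring gene spp-14. The vacuolar ATPase, a proton pump of most cells, had 4 of 21 genes bound, 19.05% (Fisher exact test, adjusted p = 0.84). Of the lists of other tissues, 2 were bound less often than other genes. No member of 31 hypodermis and cuticle genes or of 30 germ line genes was bound, with upper 95% Wilson limits of 11.03% and 11.4% (Fisher exact tests, adjusted p = 0.010 for each). For both, the call did not hold when shifted summits served as the comparison (permutation adjusted p = 0.29 and 0.40). Shifted summits gave 7.14% and 6.66% on average, against 17.05% in other genes. That comparison thus asks another question and leaves little room to show a shortfall. For hypodermis the call also did not hold without replicate 1 (3.23%, Fisher exact test, adjusted p = 0.072). The bound GATA factor gene elt-3 was counted among the intestinal regulators and not in the hypodermis list. Of 30 neuronal genes 1 was bound, unc-31 (signal 157, at an internal transcript start), a share of 3.33% that missed the threshold after adjustment (Fisher exact test, p = 0.049, adjusted p = 0.071). Body wall muscle had 3 of 24 bound, with deb-1 first (signal 229), and pharynx 2 of 20, pha-4 (signal 335) and pha-2 (signal 164). Neither differed from other genes (Fisher exact tests, adjusted p = 0.84 and 0.74).

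**Figure D4:**
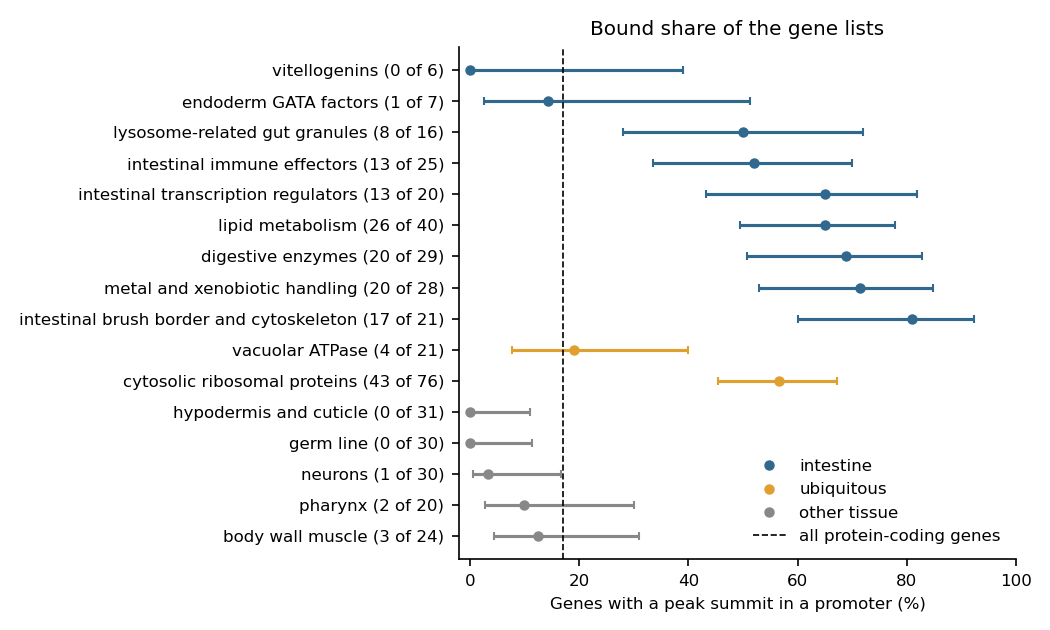
Share of each gene list with an ELT-2 summit in a promoter, in percent, with 95% Wilson intervals. Colours separate intestinal lists, ubiquitous complexes and other tissues, and the dashed line is the 17.03% of all protein-coding genes. The intestinal lists other than vitellogenins and endoderm GATA factors lie at 50% or more, and ribosomal proteins at 56.6%.

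Cytosolic ribosomal proteins, a set used by every cell, had 43 of 76 genes bound, 56.6% against 16.9% of other genes, with the smallest p of all lists (Fisher exact test, adjusted p = 1.1e-13). With each summit given only to the nearest 5′ end, the share fell to 34.2% against 15.04% (Fisher exact test, adjusted p = 7.2e-05), no longer the smallest p. The strongest peaks lay 284 bp upstream of rpl-3 (signal 1552), 224 bp upstream of rpl-22 (signal 1154), 288 bp upstream of rpl-20 (signal 1105) and 474 bp upstream of rpl-35 (signal 1070). Those at rpl-22 and rpl-20 lay nearer to the neighbours ify-1 and Y17G9B.5. Of the 4 peaks 0 held a GATA hexamer within 150 bp of the summit. Over all 41 peaks in promoters of ribosomal protein genes, 2 held it within 50 bp of the summit, 4.88% (95% Wilson interval 1.35 to 16.1), equal to the share of their flanks. In other promoter peaks it was 42.9% (Fisher exact test, two-sided, p = 7.5e-08).

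**Figure D5:**
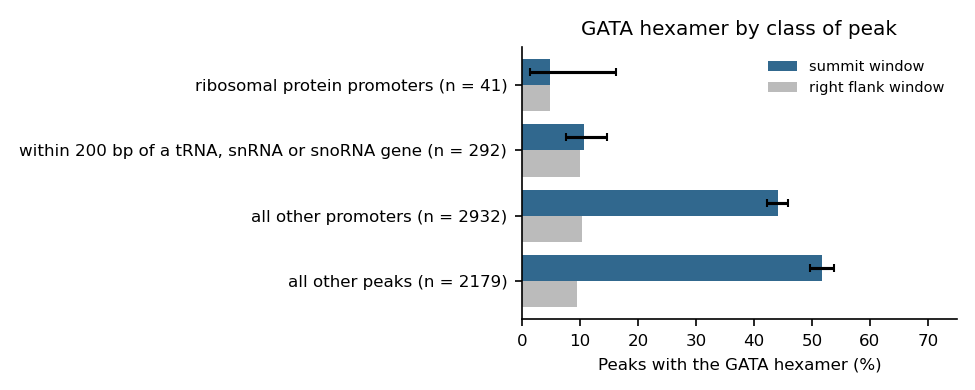
Share of ELT-2 peaks with the GATA hexamer within 50 bp of the summit, in percent (blue, with 95% Wilson intervals), and in the right flank window (grey), for 4 classes of peak. At ribosomal protein promoters, 4.88%, and near tRNA, snRNA or snoRNA genes, 10.6%, the summit share equals or nears the flank share, against 44.1% at all other promoters. The 10.6% averages unlike classes, with 18.1% at tRNA, 2.27% at snoRNA and 0% at snRNA summits.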

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

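A signal appeared in data that the comparisons above leave aside, the 11390 peaks of the pooled relaxed list that fell below the thresholded list. Of the 11389 with a complete flank window, 16.3% held the GATA hexamer within 50 bp of the summit (95% Wilson interval 15.6 to 17), against 9.07% in the right flank (exact McNemar test, two-sided, p = 2.9e-62). This comparison was chosen after the thresholded list had been examined. In 10 equal parts of the pooled list by signal, the share fell from 53.5% in the strongest to 30.4% in the part with ranks 5053 to 6735, which begins just inside the thresholded list. It was 22.1% and 16.8% in the following parts and 11.8% in the weakest, against a flank of 8.67%. No biological explanation was tested, as the study has 1 group.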

How the results depend on the processing

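Of 49 alternative values of the main results, 47 kept their direction and their side of the threshold, or for counts stayed within 1.5 times. The exceptions were counts of bound genes, 1769 with the 2721 strongest peaks and 1384 with only peaks that hold the GATA hexamer, against 3401. Both follow from using fewer peaks. Replicate agreement ranged from 71.6% within 50 bp to 85.05% for any overlap, and promoter share from 44.3% to 79.0% as the window widened, while its excess over shifted summits fell from 3.11-fold to 1.37-fold. The hexamer excess over the flank was 2.84-fold with WGATAR, 3.08-fold within 100 bp and 5.42-fold within 25 bp, against 4.55-fold. With replicate 1 left out, the hexamer share was 44.4%, the promoter share 55.5%, the ratio of the X share to that of length 1.27 and the count of bound genes 3289. With replicate 2 left out, these values were 44.1%, 56.6%, 1.22 and 3397. Over single lists, 9 of 128 alternative values changed their call. With only hexamer peaks, a restriction added after seeing the data, the bound share of ribosomal proteins turned to 2.63%, below the 6.95% of other genes (Fisher exact test, adjusted p = 0.35). The gut granule list lost its call with the 2721 strongest peaks (25%, adjusted p = 0.094, Fisher exact test). The hypodermis list lost it in 4 of 8 alternatives and the germ line list in 3 of 8. For both these included the 2721 strongest peaks and the circular shifts, whose expected share is lower. Without replicate 1 the hypodermis list had 3.23% bound (adjusted p = 0.072, Fisher exact test). The cause was not tested. Depth is unknown, so what it limits cannot be stated.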

Other observations

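The tests of gene families, small RNA genes, single loci and the gap around elt-2 were chosen after the peak lists had been examined, as was that of ubiquitous genes with summits given to the nearest 5′ end, while the other tests on the ribosomal protein and signal patterns were set before their own values were seen. Gene families defined by their symbols differed in how often they were bound. Among 117 families of at least 15 members sharing a symbol stem, 14 were bound more often than other genes and 26 less often (Fisher exact tests, two-sided, Benjamini-Hochberg over 117). Some of the former, such as rpl, rps and asp, are also in the fixed lists. The UDP-glucuronosyltransferase genes (ugt), which conjugate foreign compounds, were bound in 34 of 67 cases (50.7%, adjusted p = 1.4e-08, Fisher exact test), the cytochrome P450 genes (cyp) in 25 of 74 (33.8%, adjusted p = 0.0035), the short-chain dehydrogenase genes (dhs) in 14 of 30 (46.7%, adjusted p = 0.0014) and the nuclear receptor genes (nhr) in 66 of 269 (24.5%, adjusted p = 0.0092). Also higher were the F-box family fbxa and the chaperone families dnj and hsp, and lower the F-box family fbxb and the histone genes (his). Predicted chemoreceptor families were among the lower ones, with str at 3 of 193 (1.55%, adjusted p = 3.8e-10, Fisher exact test) and srh at 8 of 220 (3.64%, adjusted p = 4.4e-08). Collagen genes (col) had 5 of 156 bound (3.21%, adjusted p = 3.3e-06, Fisher exact test) and neuropeptide genes (nlp) 1 of 71 (1.41%, adjusted p = 0.00049). Members of a family often lie side by side and share promoters, so they are not independent.

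Small RNA genes transcribed in every tissue were also marked. Summits lay within 200 bp of tRNA genes in 160 cases, 10.1 times the mean of circular shifts, of snoRNA genes in 88, 8.92 times, and of snRNA genes in 45, 12.9 times. For each the two-sided permutation p was 0.001, the smallest 1000 shifts can give, and 0.0011 after adjustment over 10 classes. Pseudogenes and piRNA genes went the other way, at 0.324 and 0.503 times, with the same p. The miRNA, lincRNA, antisense RNA and ncRNA classes lay between, at 2.64 to 2.67 times, also with that p. Circular shifts do not keep the gathering of summits at protein-coding promoters, which was 2.16-fold, or 3.11-fold in the narrowest window. An excess of 2.64 to 2.67 times cannot be told apart from it here. No summit lay near the 20 rRNA genes (two-sided permutation p = 0.70). The hexamer stood at 0% of the snRNA summits, 2.27% of the snoRNA summits and 18.1% of the tRNA summits. Over the 292 peaks near any of these 3 classes it was 10.6%, against 9.93% in their flanks and 44.1% at all other promoters. In the peaks near these genes or at ribosomal protein promoters, 332 in all, the first hexamer by p was ACCACT, in 20.5% against 2.41% of flanks (Fisher exact test, adjusted p = 1.5e-17). By fold others exceeded it, with CACGCG in 9.64% against 0.151%. The complement of ACCACT, AGTGGT, overlaps the end of the A box, the internal promoter element of tRNA genes.

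More widely, 1433 peaks, 26.3%, held no WGATAR within 100 bp of the summit, and 1210 of these lay neither near such a small RNA gene nor at a ribosomal protein promoter. Ordered by p and not by fold, the first hexamers of the 1433 were GAGAGA, in 23.1% against 5.55% of flanks, and TGCGTC, in 14.9% against 2.09% (Fisher exact tests, adjusted p = 8.7e-58 and 1.1e-52). Both were also more frequent over all ELT-2 peaks, GAGAGA with 15.8% against 5.02% and TGCGTC with 8.52% against 1.92%. Of the 1433 summits 63.5% lay in promoters. The flanks were not matched to them for location or base composition, nor chosen for lacking WGATAR. Whether these hexamers belong to the peaks or to promoter sequence in general was therefore not tested. The median signal of the 1433 was 224, against 259 for all other peaks.

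Some loci were picked out after their values were seen. The densest 10000 bp, on chromosome X from 7314709 to 7323722, held 10 summits among the saposin-like genes spp-2, spp-3, spp-4, spp-5 and spp-6, where the highest count over 1000 sets of uniform random positions was 9. Uniform positions lack the gathering of peaks at promoters, so this comparison cannot show that the density is unusual. The nearest ELT-2 peak upstream of the yolk gene vit-3, 3901 bp away (signal 1002, rank 121), lay in the promoter of ckc-1, as that of vit-1 lay in that of spp-14. The gut esterase gene ges-1 had its ELT-2 peak 1115 bp upstream (signal 295), just outside the window that counted genes as bound. Replicate 1 was the only list whose peaks differed between builds in width, with a median of 404 bp on ce10 and 400 bp on ce11, and 22.5% of its ce11 signal values recurred among those on ce10 to 3 decimals. For replicate 2 the share was 94.6% and the width 396 bp on both.

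For the first pattern weighed, the peaks at ribosomal protein promoters, recruitment through the GATA hexamer is argued against by its presence at 4.88% of their summits, and peaks of closer neighbours, as the whole cause, by the 34.2% of these genes that stayed bound when each summit went to the nearest 5′ end (Fisher exact test, p = 3.2e-05), though the fall from 56.6% leaves them open for part of the count. Binding at active promoters of ubiquitous genes in general was not decided by proteasome and translation factor genes. These were bound in 33.3% of cases, above the 16.97% of other genes (Fisher exact test, p = 0.00075), the outcome set beforehand for this cause. Their upper 95% Wilson limit of 44.8% lay below the 56.6% of ribosomal proteins, the outcome set against it. Both outcomes were met, so no conclusion on this cause follows. For the 34.2% this cause stays open too. With each summit given to the nearest 5′ end, proteasome and translation factor genes were bound in 27.8% of cases (upper limit 39.05%). Mitochondrial ribosomal proteins were bound in 14.3% (upper limit 24.3%), and transcription was not measured. In the promoter window mitochondrial ribosomal proteins, at 24.3% (Fisher exact test, p = 0.11), and the vacuolar ATPase, at 19.05% (Fisher exact test, adjusted p = 0.84), did not pass the test. These peaks may reflect contact with highly transcribed DNA rather than sequence recognition, which a control precipitation of free GFP, not used here, would test.

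The second pattern is the lack of any listed peak around elt-2. The stretch without a summit in any ce11 list was 53.5 kb long and held 6 genes. Gaps at least as long as the one of 73.9 kb in the pooled list contained 3.48% of protein-coding genes. Taken by each replicate's own gap, the figures were 2.72% for replicate 1 (73.9 kb) and 5.55% for replicate 2 (53.5 kb). Chance sparsity thus cannot be excluded. The transgene adds copies of at least elt-2, so a raised control there could have kept peaks from being called, and as the control reads were not used here this cannot be told apart from absence of binding. The missing peaks at elt-2 and elt-4 are therefore no evidence on autoregulation.

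The third pattern is that stronger peaks hold the hexamer more often. Base composition of strong peaks is argued against, since the number of 48 composition-matched hexamers without a GAT core went the other way with signal (Spearman rho across peaks = -0.0632, two-sided permutation p = 0.0001, the smallest 10000 permutations can give). Imprecise summits of weak peaks are argued against by a rho of 0.131 in a window of 200 bp either side, close to the 0.137 of the planned window. No biological explanation was tested.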
